A study of Mus musculus with 24 samples.

How the data were processed

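RNA was measured by poly(A)-selected RNA sequencing in mouse embryonic stem cells (C57BL/6) and in embryoid bodies grown from them, in 24 libraries. Per the labels' protocols, cells were grown with serum and LIF on feeder layers of embryonic fibroblasts, and the gene Eed was deleted in a conditional line with 800 nM 4-hydroxytamoxifen. Per the labels, 4 genotypes (f/f, the untreated conditional line; KO; KO with re-expressed wild-type EED, here KO+WT; and KO with the form labelled N-KR, here KO+N-KR) were sampled in 3 states (the state labelled 3i, and embryoid bodies at day 1 and day 2), with 2 libraries in each of the 12 groups. The labels do not spell out N-KR. Groups were taken from the sample titles, because the genotype field of both rescue lines names the knockout alone. Only f/f was grown without tamoxifen, so in comparisons with f/f, tamoxifen, the history of each line and the genotype cannot be told apart. KO, KO+WT and KO+N-KR were all treated, so between them tamoxifen did not differ, but line history and genotype cannot be told apart.

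The authors deposited 1 table of raw read counts for 23284 gene symbols in 30 columns. The 24 columns whose names match the library names in the labels were used, and the other 6 were not used here. Per the submitters' processing notes, reads were processed with STAR 2.5.2b and DESeq2, and the build was mm9. The counting tool, its strand setting, the DESeq2 version and the gene annotation are not given in the sources used here, so overlapping and antisense genes cannot be separated, and families of near-identical copies (Xlr, Zscan4, Tcstv3) are uncertain member by member. Library totals ran from 7553683 to 14426034 counts. The reference annotation used here, GRCm38, differs from that build, so no coordinates are given, and it served only to find which genes neighbour each other.

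The 2 libraries of each group were compared before any test. The variance of their count differences was 1.10 to 1.18 times that of binomial sampling (genes with at least 20 reads per pair), against 3.48 to 15.5 times between genotypes within a state, and Pearson's r of their log2 CPM was 0.998 in each group. Nothing in the labels says that they came from separate cultures. They were therefore summed and counted as 1 sample, which left 12 samples of 18017598 to 25160294 counts and 1 sample per genotype and state.

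Because of that, results are given in 3 ways. First, an additive model of genotype and state was fitted to the 12 samples with edgeR (4.0.16, TMM scaling, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05), with 14970 genes tested and 6 residual degrees of freedom. Its common coefficient of variation was 7.94%. It uses the 3 states as the 3 samples of a genotype and the 4 genotypes as the 4 samples of a state, so its p-values measure how evenly a difference between single lines recurs over states, and not the spread between independent lines. It was chosen after seeing the data, as were the 12 sums. Standard errors were derived from the fold change and its F statistic. Second, within a state a gene was called by size alone: at least 2-fold, with at least 5 CPM in the higher sample (TMM-scaled, prior count 2 for the ratio), without a p-value. Last, the design written before the data were examined was fitted to the 24 libraries as 12 groups of 2 (14619 genes tested, 12 residual degrees of freedom, coefficient of variation 0.988%). Its p-values compare these RNA samples against noise near that of repeated sequencing, not the genotypes.

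Both fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed in KO against f/f. At 1.5-fold, 2-fold and 4-fold, the 12-sample fit over 3 states recovered 79.5%, 95.5% and 100% of them, with 5, 10 and 14 false calls among 14866, 14866 and 14878 genes. The 24-library fit at 3i recovered 86%, 98.5% and 100%, with 8, 10 and 13 false calls among 14169, 14165 and 14156 genes. Genes with low counts were not among those changed. Means were shared by all groups for the 24-library fit and by the genotypes of a state for the 12-sample fit. In the 12-sample simulation no genotype difference varied between states, so recovery in the real data can be lower.

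Gene lists were fixed before the data were examined: PRC2 subunits, PRC1 subunits, SCF ubiquitin ligase, naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, endoderm, mesoderm, neuroectoderm, trophoblast, germline, 2-cell-like, Hox genes, textbook Polycomb targets outside Hox, imprinted genes, FGF-ERK feedback, WNT feedback, p53 targets, heat shock and unfolded protein, proteasome, ribosomal proteins, the mitochondrial genome, replication-dependent histones, housekeeping, embryonic fibroblasts (feeders), parietal endoderm, endothelium and blood, and neurons. None of the 10 mitochondrial genes was in the table, so 28 lists were tested with limma's camera (3.58.1, preset correlation 0.01, adjusted over the lists) and again with an estimated correlation. Within a state, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of these samples. Lists of genes higher in KO at 3i or changed in f/f embryoid bodies were derived from comparisons of KO and f/f libraries. They were tested in KO+N-KR against KO+WT, which shares none of those libraries. Correlations between comparisons that share the KO samples were set beside 20 simulations of unchanged groups.

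Genes named in the text follow a rule written before the data were examined. For each of KO against f/f, KO+WT against KO and KO+N-KR against KO+WT in each state, and for day 2 against 3i in f/f, it takes the 8 highest and the 8 lowest fold changes among genes past the threshold in the 24-library fit, with at least 5 CPM and the same direction in both libraries, leaving out predicted and unnamed loci. It adds up to 4 members of each list past the threshold, and a fixed set of PRC2, pluripotency and lineage genes.

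Alternatives were RLE scaling, library totals alone, no filter on low counts, DESeq2 (1.42.0), the replicate number as a block, the compared groups alone, a minimum of 2-fold, and leaving out each library. Those for the 12-sample fit and the rule of size, including leaving out each state, were added after seeing the data. Statistics were computed in R 4.3.3, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.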

Results

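Poly(A) RNA was sequenced from mouse embryonic stem cells and from embryoid bodies grown from them. The 24 libraries fell into 12 groups of 2: the untreated conditional line (f/f), the line deleted for Eed by tamoxifen (KO), and KO cells with re-expressed wild-type EED (KO+WT) or with the form labelled N-KR (KO+N-KR), each in the state labelled 3i and as embryoid bodies at day 1 and day 2. EED is a core subunit of PRC2, the Polycomb complex that methylates histone H3, and the series title links SKP1A, a subunit of SCF ubiquitin ligases, to the loss of PRC2 and the activation of genes that Polycomb silences. Library totals ran from 7553683 to 14426034 counts. The 2 libraries of a group differed by little more than sampling noise (1.10 to 1.18 times the binomial variance, against 3.48 to 15.5 times between genotypes) and were counted as 1 sample. A genotype in 1 state therefore has no biological replicate. Fold changes below are log2 values ± SE over the 3 states of each line, 1 sample each, with p-values from edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. Values within a state are levels of single samples, in CPM with TMM scaling, so they differ slightly from the CPM of the library total drawn for Eed in each library.

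Eed, the deleted gene, stood at 175, 219 and 131 CPM in f/f at 3i, day 1 and day 2, and at 138, 173 and 102 CPM in KO. Across states Eed fell in KO against f/f (-0.35 ± 0.10, adjusted p = 0.0463). Reads were counted over the whole gene and the deleted part is not stated in the labels, so this level is no check of the deletion. In KO+WT, Eed rose against KO (1.17 ± 0.10, adjusted p = 1.75e-05) to 387, 372 and 188 CPM. In KO+N-KR it stood at 168, 181 and 122 CPM, below KO+WT (-0.97 ± 0.10, adjusted p = 0.000287) and not past the threshold against KO (0.20 ± 0.10, adjusted p = 0.196). The labels do not say whether reads from the added EED sequence would be counted, so this level does not measure how much was added, and the libraries are called here by their label. The Eed call in KO was lost under library totals alone (-0.29, adjusted p = 0.0725) and without day 1 (-0.35, adjusted p = 0.294) or day 2 (-0.35, adjusted p = 0.0608). Skp1a did not pass the test in KO (-0.13 ± 0.05, adjusted p = 0.122), with 345.1, 361 and 385 CPM at 3i, day 1 and day 2 against 389, 406 and 395 CPM in f/f.

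**Figure D1:**
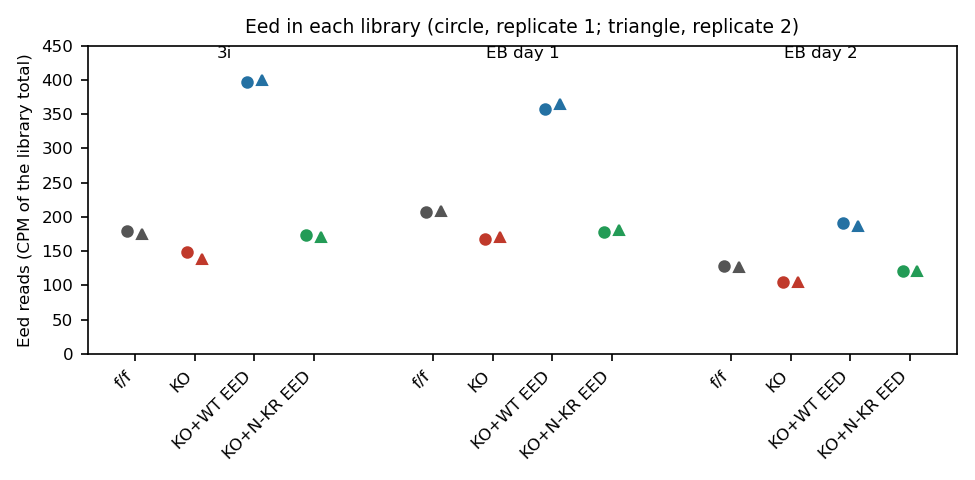
Eed level (y axis, CPM of the library total) in each of the 24 libraries, grouped by genotype and state (x axis). Each marker is 1 library, a circle for replicate 1 and a triangle for replicate 2. Within each state, the libraries labelled KO+N-KR lie near those of KO and f/f, and the KO+WT libraries lie above them.

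Embryoid body formation was compared with 3i across the 4 genotypes to show which programs changed as cells left the 3i state. At day 2, 13 of 15 naive pluripotency genes fell, among them Klf4 (-4.78 ± 0.07), Tfcp2l1 (-3.68 ± 0.20), Tbx3 (-3.59 ± 0.18) and Nanog (-1.66 ± 0.11), all transcription factors of the naive network. Of 15 formative and primed epiblast genes, 14 rose, with Fgf5 (7.28 ± 0.25), the transcription factors Pou3f1 (4.40 ± 0.16) and Otx2 (3.11 ± 0.18), and the de novo DNA methyltransferase Dnmt3b (3.68 ± 0.21). Wnt8a (6.99 ± 0.36), Vrtn (6.96 ± 0.20) and Pax6 (6.39 ± 0.44), an eye and neural regulator, rose from near 0. The counts adjusted over the list alone were 13 fallen and 1 risen naive genes and 14 risen formative genes. At day 1, 13 naive genes had fallen and 1 had risen, and 15 formative genes had risen (13, 1 and 15 when adjusted over the list alone). Pou5f1, a core pluripotency factor, did not pass at day 2 (-0.09 ± 0.04, adjusted p = 0.0689).

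Feeder fibroblast markers fell alongside: 14 of 16 at day 1, and 12 at day 2 where 2 rose, with the same counts adjusted over the list alone. Col1a1 dropped (-3.61 ± 0.15) from 243 to 12.2 CPM in f/f, and Acta2 (-5.84 ± 0.20) from 38.1 to 0.139 CPM. Of 25 proteasome genes, 24 rose at day 1 and 19 at day 2 (24 and 20 adjusted over the list alone), a list that camera called at day 1 (adjusted p = 6.88e-08, and 0.477 with an estimated correlation) and not at day 2 (adjusted p = 0.0792). Of 28 imprinted genes, 13 and 17 rose and 8 and 6 fell (the same counts over the list alone), with camera at 0.00988 and 0.0098, and 0.1 and 0.159 with an estimated correlation. Imprinted genes that rose at day 2 included Mest (2.20 ± 0.12), Snrpn (1.80 ± 0.05) and Peg10 (1.65 ± 0.09). In all, 4777 genes rose and 5121 fell at day 1, and 4973 and 4587 at day 2, and under library totals alone 3976 and 6012, and 4555 and 5043. Camera, a test of a list against other genes, called 9 and 6 lists at the 2 days, and 0 with an estimated correlation. For naive genes the adjusted p was 5.74e-07 and 1.54e-14 against 0.404 and 0.176 with an estimated correlation. For formative genes it was 1.22e-21 and 3.45e-22 against 0.0716 and 0.12, and for feeder markers 1.48e-12 and 7.05e-10 against 0.1 and 0.176. Under library totals alone, the median of all genes at day 1 moved to -0.11.

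KO was compared with f/f to show which genes changed with the deletion of Eed. Across states 694 genes rose and 686 fell, 103 and 15 of them by at least 2-fold. Sfmbt2, an imprinted gene for a Polycomb group protein, rose (1.86 ± 0.29, adjusted p = 0.00719) to 35.7, 52.2 and 98.8 CPM, against 20.3, 15.7 and 14.7 CPM in f/f. Plagl1, an imprinted zinc finger gene, rose too (1.20 ± 0.21, adjusted p = 0.0104). Lefty2, a secreted inhibitor of Nodal signalling (1.22 ± 0.15, adjusted p = 0.00439), the transcription factors Zfp521 (1.72 ± 0.30) and Meis2 (1.35 ± 0.33), the helix-loop-helix inhibitor Id2 (1.46 ± 0.35), the matrix protein gene Cyr61 (1.57 ± 0.23), carbonic anhydrase gene Car12 (1.90 ± 0.29), Lrrc15 (1.95 ± 0.35), the ephrin gene Efnb3 (1.27 ± 0.20), Sh3pxd2b (1.37 ± 0.18) and the kinase gene Nrk (1.21 ± 0.35) also rose, with adjusted p from 0.00439 to 0.0471. The genes that fell included the Notch ligand Dll1 (-1.498 ± 0.30, adjusted p = 0.0144), the neuroendocrine transcription factor Insm1 (-1.13 ± 0.19, adjusted p = 0.00774), Ccno (-1.25 ± 0.25), the zinc finger gene Wt1 (-1.10 ± 0.19), the ectonucleotidase Nt5e (-1.18 ± 0.13), the stress sensor Gadd45g (-1.19 ± 0.19), the semaphorin Sema6a (-1.03 ± 0.25) and Bhlhe41 (-1.53 ± 0.22), with adjusted p from 0.00399 to 0.0261.

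By group, 3 of 15 naive pluripotency genes rose in KO, Klf4 (0.45 ± 0.07), Prdm14 (0.93 ± 0.26) and Tcl1 (0.73 ± 0.21), and Fgf4 fell (-0.33). Adjusted over the list alone, 7 rose and 1 fell. Of 15 formative genes 2 fell, Lef1 (-0.82 ± 0.24) and Pou3f1 (-0.66 ± 0.17), also when adjusted over the list alone, and 2 of 10 general pluripotency genes fell, Pou5f1 among them (-0.24 ± 0.05, adjusted p = 0.0161), with 4 over the list alone. Of 18 endoderm genes 4 rose (6 adjusted over the list alone), Sox7 (1.42 ± 0.35), Dab2 (0.57 ± 0.17), Lama1 (0.45 ± 0.12) and Lamb1 (0.21), and so did 2 of 8 parietal endoderm genes (5 adjusted over the list alone), both counted in the endoderm list. Of 12 PRC2 subunits 3 fell, Eed, Rbbp4 (-0.29 ± 0.05) and Rbbp7 (-0.27 ± 0.05), and 4 when adjusted over the list alone, and of 21 PRC1 subunits 6 fell, Pcgf1 among them (-0.48), and 2 rose (7 and 4 over the list alone). Of 26 ribosomal protein genes 12 fell (24 adjusted over the list alone), with Rpl13 at -0.24, as did 4 of 25 proteasome genes (4 over the list alone) and the housekeeping genes Hprt (-0.30) and Pgk1 (-0.32) among 10 (5 fell and 1 rose over the list alone). Of 28 imprinted genes 4 rose and 1 fell (5 and 1 over the list alone). Of 45 textbook Polycomb targets 3 rose, Sox7, Meis2 and the T-box gene Tbx4 (0.89), and none fell, also over the list alone. None of 16 feeder markers passed, also over the list alone, and their median was 0.30.

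Single members passed in other groups: Tbx4 rose among 16 mesoderm genes and Brdt (0.94) among 16 germline genes (2 over the list alone), Pmaip1 rose (0.32) among 14 p53 targets (0 over the list alone), and 1 gene each fell among 10 trophoblast, 14 FGF-ERK feedback and 12 WNT feedback genes, unchanged over the list alone. No member passed, in either adjustment, among 12 SCF ubiquitin ligase, 13 primitive streak, 13 neuroectoderm, 7 2-cell-like, 13 Hox, 14 heat shock, 11 replication-dependent histone, 6 endothelial and blood and 7 neuron genes. Camera called 7 lists: endoderm (adjusted p = 0.0203), parietal endoderm (0.0203), naive pluripotency (0.0333), feeder markers (0.0156), proteasome (1.51e-05), ribosomal proteins (7.56e-10) and housekeeping (0.0294). With an estimated correlation it called 0, with an adjusted p of 0.514 for housekeeping and 0.622 for each of the others. Not past the threshold were Gata3 (1.53 ± 0.57, adjusted p = 0.103), Bmi1 (0.69 ± 0.25, adjusted p = 0.0999), the cell cycle inhibitor gene Cdkn2a (0.49 ± 0.18, adjusted p = 0.094), H19 (0.79 ± 0.25, adjusted p = 0.0674) and Dnmt3b (-0.39 ± 0.22, adjusted p = 0.285). Under library totals alone the split of calls moved from 694 higher and 686 lower to 1083 and 327. Without day 1, 0 genes passed in edgeR (lowest adjusted p = 0.0844, with 2272 of 15111 genes at an unadjusted p under 0.05) and 124 in DESeq2. Without day 2, 339 passed, with replicate 2 libraries alone 808, and with KO and f/f alone 782.

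Within single states, more genes differed between KO and f/f at day 2 than before. By size, 29 genes were higher and 26 lower at 3i, 39 and 19 at day 1, and 198 and 18 at day 2. The 198 genes higher at day 2 had median log2 ratios of 0.30 at 3i and 0.58 at day 1, before the day 2 at which they were chosen. Among them were Sfmbt2, the trophoblast and endothelial regulator Gata3 (5.62 CPM in KO, 0.462 in f/f), Lrrc15 (15.7 against 1.71 CPM), Nrk (18.0 against 3.51 CPM) and Car12 (8.31 against 1.29 CPM). At day 2 the median log2 ratio was 1.12 for 10 trophoblast genes, 1.12 for 16 mesoderm genes, 1.02 for 13 Hox genes and 0.79 for 45 textbook Polycomb targets, at percentiles 100, 100, 99.7 and 100 of 10000 random lists matched on expression. In f/f itself, from 3i to day 2, the medians of these lists were -1.25, 0.25, -0.49 and 0.01. For trophoblast and Hox genes, a higher value in KO than in f/f at day 2 is therefore not by itself a rise from 3i. Camera values within a state come from the fit over the 24 libraries, so they compare these RNA samples and not the genotypes. At day 2 camera called the trophoblast, mesoderm and Polycomb target lists (adjusted p = 9.88e-05, 0.00523 and 0.000334, and 0.00479, 0.024 and 0.00468 with an estimated correlation). Hox genes were not called (0.0722, and 0.104 with an estimated correlation). Across states, camera called none of the trophoblast, mesoderm, Polycomb target and Hox lists (adjusted p = 0.378, 0.168, 0.149 and 0.952). At day 1 Hox genes lay the other way, at -0.64 (percentile 0.04), trophoblast genes at -0.13 (percentile 5.27), mesoderm genes at 0.34 (percentile 92.2) and Polycomb targets at 0.31 (percentile 99.1), and camera called none of these 4 (adjusted p = 0.478, 0.876, 0.381 and 0.102). At day 2 formative genes lay at -0.56 (percentile 0) and naive genes at 0.46 (percentile 100). Dnmt3b stood at 429 CPM in KO against 961 CPM in f/f. Feeder markers were higher in KO at day 2 as well, with a median of 0.57 (percentile 99.96; camera adjusted p = 0.0384, and 0.0571 with an estimated correlation). At 3i the Polycomb targets lay lower in KO than in f/f, at -0.29 (percentile 0), and trophoblast genes at -0.23 (percentile 1.48), but camera called neither (adjusted p = 0.863 and 0.723). The immediate early genes Egr1 (476 against 140 CPM), Fos (424 against 194 CPM) and Fosb (73.0 against 14.9 CPM) were higher in KO at 3i, and both rescue lines were near KO, with Egr1 at 433 CPM in KO+WT and 385 CPM in KO+N-KR. Under library totals alone, 34 genes were higher and 18 lower at 3i. With a minimum of 10 CPM, 115 genes in all differed by size at day 2, in place of 216, 36 at 3i and 27 at day 1.

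**Figure D2:**
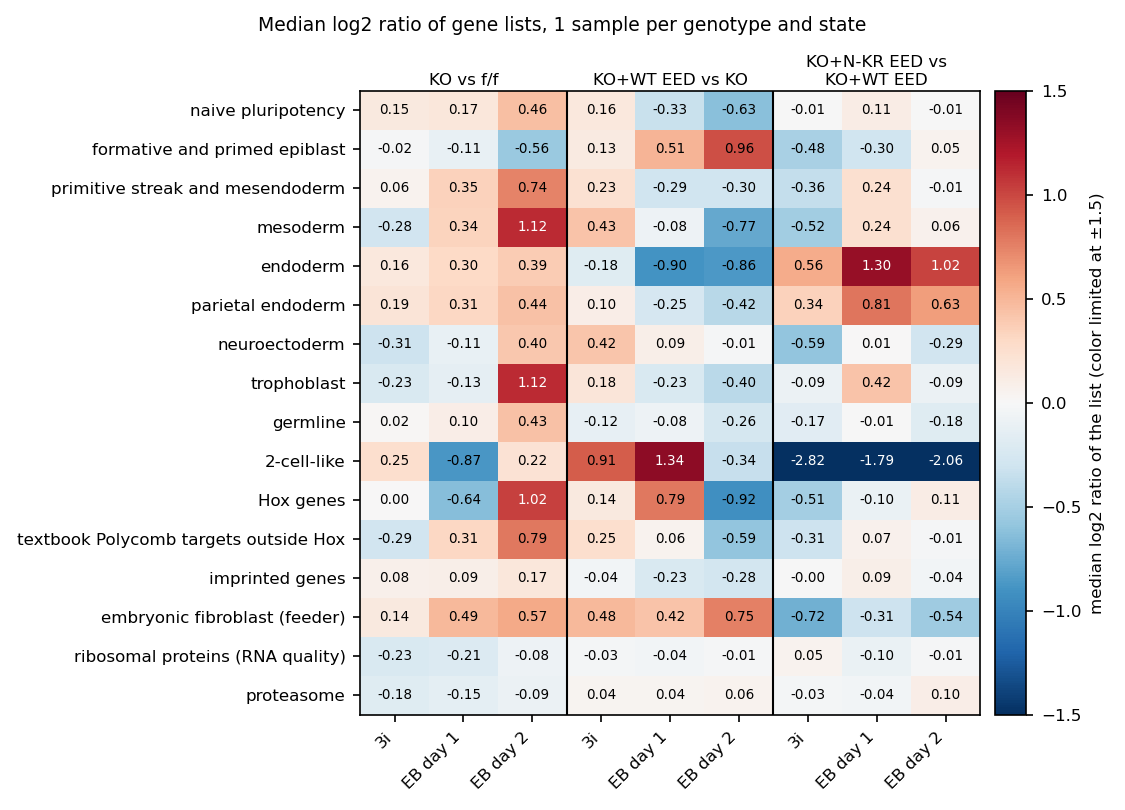
Median log2 ratio (color) of gene lists (y axis) in 3 comparisons of genotypes at 3i, day 1 and day 2 (x axis), from 1 summed sample per genotype and state. In KO against f/f at day 2, trophoblast (1.12), mesoderm (1.12) and Hox (1.02) genes stand higher, and in KO+N-KR against KO+WT endoderm genes stand higher and 2-cell-like genes lower in each state.

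KO+WT was compared with KO to show what differed when wild-type EED was put back. Across states 1065 genes rose and 1357 fell, 107 and 141 of them by at least 2-fold. Sfmbt2 fell (-1.97 ± 0.30, adjusted p = 0.000896) to 20.7, 12.1 and 14.7 CPM, and Plagl1 (-0.83 ± 0.21), H19 (-0.91 ± 0.26) and Cdkn2a (-0.98 ± 0.18, adjusted p = 0.00322) fell. Insm1 (2.19 ± 0.18, adjusted p = 1.31e-05), the lysophospholipase gene Enpp2 (2.21 ± 0.17, adjusted p = 1.12e-05), Ccno (1.94 ± 0.24), Sema6a (1.75 ± 0.24), Dll1 (1.73 ± 0.30) and Gadd45g (1.63 ± 0.18) rose. Of 15 formative genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with Wnt8a (1.56 ± 0.28), Pou3f1 (1.32 ± 0.16), Lef1 (1.10 ± 0.24), Fgf5 (0.94 ± 0.19) and Dnmt3b (0.85 ± 0.23) among those that rose. Of 18 endoderm genes 9 fell (10 adjusted over the list alone), among them the endocytic receptor gene Cubn (-1.39 ± 0.16, adjusted p = 0.000185), the endoderm regulators Gata6 (-1.41 ± 0.34), Gata4 (-1.20 ± 0.27) and Sox7 (-1.16 ± 0.34), and the basement membrane collagen gene Col4a1 (-0.63 ± 0.10). Of 10 general pluripotency genes 4 rose (6 over the list alone), with Pou5f1 at 0.23 ± 0.05. Of 28 imprinted genes 8 fell and 2 rose (11 and 3 over the list alone), with Grb10 higher (0.99 ± 0.12).

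Feeder markers moved with these groups: 7 of 16 rose (12 adjusted over the list alone), with Col3a1 at 0.74 ± 0.13 and Col1a1 at 0.66 ± 0.16. Bmi1 (-0.98 ± 0.26), Prdm14 (-0.83 ± 0.26) and the mesendoderm regulator Eomes (-1.13 ± 0.18) fell as well. Of 45 textbook Polycomb targets 8 fell and 5 rose (9 and 6 over the list alone), with Meis2 (-1.24) lower and the neural gene Neurog1 (1.49) and Msx1 (1.35) higher. Among the lowest fold changes were those of neighbouring Xlr genes on the X chromosome, with Xlr5a at -6.37 ± 0.26 (adjusted p = 1.47e-08) and Xlr3a at -3.54 ± 0.16, whose near-identical copies make single members uncertain. Camera called 4 lists, formative (adjusted p = 2.62e-05), endoderm (3.32e-05), feeder (0.000339) and general pluripotency (0.0283), and 0 with an estimated correlation, where the adjusted p was 0.426 for each. By size, 47 genes were higher and 34 lower at 3i, 70 and 109 at day 1, and 76 and 215 at day 2. With a minimum of 10 CPM the totals were 41, 119 and 175, in place of 81, 179 and 291. Without day 1 225 genes passed and without day 2 1263, in place of 2422.

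Of the 694 genes higher in KO than in f/f, 319 (46%) were lower in KO+WT than in KO, where independent lists would share 62.9, and of the 686 lower in KO, 273 (39.8%) were higher in KO+WT, against 48.8. Both comparisons use the same KO samples, and how much of the overlap comes from this was not measured. Across genes the correlation of fold changes was -0.48 (simulated -0.50), and the covariance was -0.062 against -0.021 in simulation. Between comparisons that share no KO sample, Pearson's r across 10738 genes, which are not independent replicates, ran from -0.17 (KO at 3i and KO+WT at day 1) to -0.48 (KO at day 2 and KO+WT at day 1). For KO+N-KR the overlap with KO was 316 of 694 (45.5%, independent lists 62.4) and 280 of 686 (40.8%, independent lists 45.8), with a covariance of -0.063 against -0.020 in simulation, and r with no shared KO sample ran from -0.09 (KO at 3i and KO+N-KR at day 1) to -0.41 (KO at day 1 and KO+N-KR at day 2). All these comparisons use the same KO line, so a lasting feature of that line would give a negative r whatever EED did. The simulated groups had no genotype effect, so a covariance larger than simulated cannot tell such a feature from a reversal by EED either. Of the 198 genes higher in KO at day 2, 118 were at least 2-fold lower than KO in KO+WT at day 2 and 124 in KO+N-KR, with medians of -1.11 and -1.15. These genes were chosen for a high value in that same KO sample, so part of the fall is built in. Against f/f, a comparison without the KO sample, their median in KO+WT was 0.26. The choice also favoured a low value in that f/f sample, so part of this median can be built in too.

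**Figure D3:**
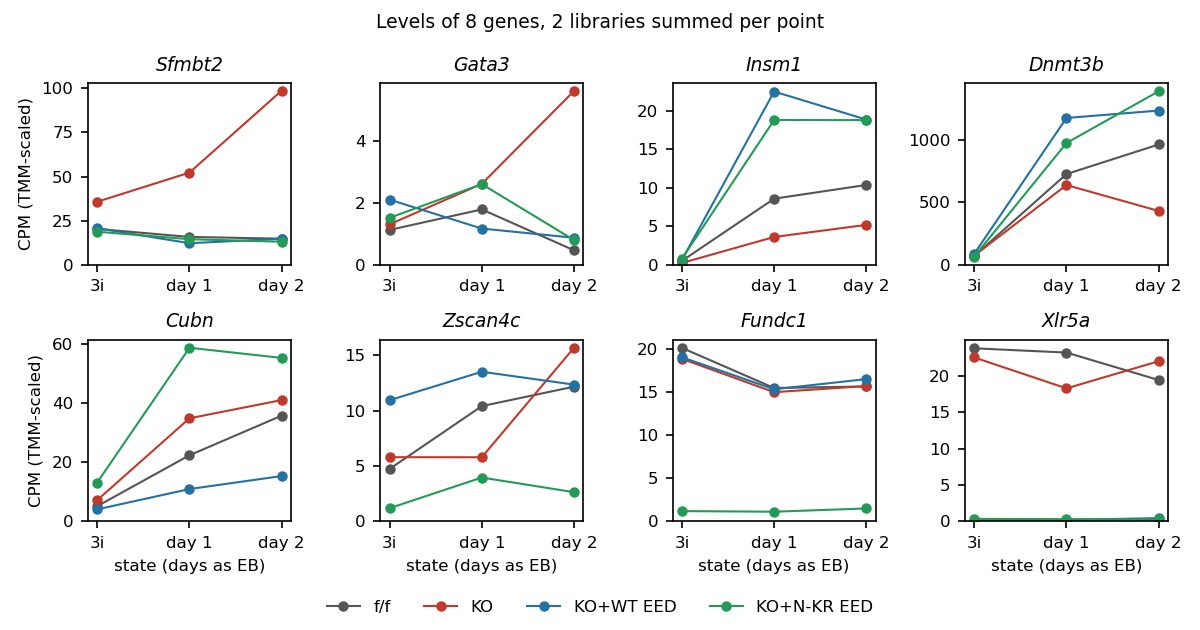
Levels of 8 genes (y axis, TMM-scaled CPM, from 0) at 3i, day 1 and day 2 (x axis) in f/f, KO, KO+WT and KO+N-KR, with 2 libraries summed per point and no error bar because each point is 1 sample. Sfmbt2 reached 98.8 CPM in KO at day 2 against 13.0 to 14.7 CPM in the other lines, Fundc1 stayed between 1.11 and 1.49 CPM in KO+N-KR, and Xlr5a lay under 0.5 CPM in both rescue lines.

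KO+N-KR was compared with KO+WT, the comparison on which the labelled form of EED bears. The counted Eed RNA was lower in KO+N-KR as well, and each genotype is 1 line. The form of EED, its amount and the history of the line therefore cannot be told apart in the differences below. Across states 44 genes rose and 40 fell, 12 and 25 of them by at least 2-fold. Of 18 endoderm genes 7 rose and none fell (15 adjusted over the list alone), with a median of 1.09. They included Cubn (2.06 ± 0.16, adjusted p = 2.7e-05), its partner Amn (1.75 ± 0.33), Foxq1 (1.497 ± 0.23), the endocytic adaptor gene Dab2 (1.29 ± 0.17), and the basement membrane genes Lama1 (0.96 ± 0.12), Col4a2 (0.88 ± 0.12) and Col4a1 (0.86 ± 0.10). Cubn stood at 13.1, 58.9 and 55.4 CPM in KO+N-KR, 4.04, 10.9 and 15.3 CPM in KO+WT, 7.17, 34.9 and 41.1 CPM in KO and 5.13, 22.4 and 35.8 CPM in f/f. Gata4 (1.11 ± 0.28, adjusted p = 0.135) and Gata6 (1.31 ± 0.35, adjusted p = 0.2) did not pass. Of 8 parietal endoderm genes, 5 of them in the endoderm list too, 4 rose (6 over the list alone), with Srgn at 1.61 ± 0.19. Of 7 2-cell-like genes 6 fell (6 over the list alone), among them Zscan4c (-2.30 ± 0.33) and Tcstv3 (-3.75 ± 0.59), which mark the rare 2-cell-like state of stem cell cultures. Outside that list the near-identical copies Zscan4e (-2.57 ± 0.30) and Zscan4b (-2.47 ± 0.31) fell as well. Levels were low: in f/f, 0 of the 7 list genes reached 5 CPM at 3i and 4 did at day 2. The correlation estimated among the 7 was 0.725, so the 6 that fell are not independent. In f/f the list rose from 3i, with medians of 1.14 at day 1 and 1.40 at day 2. Leaving out 1 state moved the endoderm count to 9 of 19 tested genes (without 3i, median 1.39), 3 of 19 (without day 1, median 0.94) or 4 of 16 (without day 2, median 0.91), the parietal endoderm count to 2 (without day 1) and the 2-cell-like count to 4 (without day 1) or 3 of 6 tested (without day 2). Camera called these 3 lists with the preset correlation (adjusted p = 2.19e-45, 6.14e-23 and 5.19e-32) and with an estimated one (adjusted p = 0.0103, 0.0139 and 0.0162).

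Feeder markers moved the other way: 1 of 16 fell, Col5a2 (-0.62 ± 0.13), and 9 when adjusted over the list alone, with a median of -0.49 and Col6a1 at -0.76 ± 0.19 (adjusted p = 0.137). Its camera call (adjusted p = 1.83e-13) had an adjusted p of 0.0939 with an estimated correlation. Of 28 imprinted genes 4 rose, Plagl1 (1.01 ± 0.20), Peg3 (0.96 ± 0.09), Impact (0.93 ± 0.08) and Zdbf2 (0.76 ± 0.07), and 2 fell, with Grb10 at -0.76 ± 0.11 (4 and 3 over the list alone; camera adjusted p = 0.0161, and 0.0988 with an estimated correlation). Formative (0 of 15 passed, median -0.15) and WNT feedback genes (0 of 12, median -0.36) were called by camera (adjusted p = 0.000661 and 0.000333), with an adjusted p of 0.413 and 0.235 with an estimated correlation. The gene with the smallest adjusted p was Fundc1, a mitochondrial outer membrane protein gene (-3.75 ± 0.14, adjusted p = 5.78e-09), at 1.18, 1.11 and 1.49 CPM in KO+N-KR and 15.0 to 20.1 CPM in the other lines. The Y-linked translation factor gene Eif2s3y rose (1.32 ± 0.07, adjusted p = 5.91e-07), and Tab1 (-0.90 ± 0.11) and Fgf17 (-0.96 ± 0.19) fell. By size, 15 genes were higher and 39 lower at 3i, 28 and 17 at day 1, and 12 and 13 at day 2, and with a minimum of 10 CPM the totals were 26, 25 and 12, in place of 54, 45 and 25. In place of 84 genes, 30 passed without day 1, 132 in DESeq2 and 200 with KO+WT and KO+N-KR alone.

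Genes chosen from the 24-library fit, at an adjusted p under 0.05 and at least 2-fold, were set beside that comparison. The 1292 tested genes induced in f/f embryoid bodies at day 2 had medians of -0.18 at 3i, -0.13 at day 1 and -0.03 at day 2 in KO+N-KR against KO+WT, with 5 risen and 13 fallen across states, and their camera call (adjusted p = 5.32e-06) had an adjusted p of 0.121 with an estimated correlation. The 131 genes higher in KO than in f/f at 3i had medians of -0.08, 0.07 and -0.02, with 3 risen and 0 fallen, and were not called (adjusted p = 0.526, and 0.859 with an estimated correlation). Nor were the 34 genes in both lists (0 passed, adjusted p = 0.526) or the 1245 genes repressed in embryoid bodies (2 rose and 2 fell, adjusted p = 0.526). These lists came from KO and f/f libraries, and none of those libraries is in the comparison of KO+N-KR with KO+WT. The spread was estimated over all 12 samples, and each genotype is 1 line.

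Against f/f, KO+WT differed in 555 genes that rose and 813 that fell, and under library totals alone in 769 and 638. Grb10, an imprinted adaptor gene, rose (1.24 ± 0.12, adjusted p = 4.3e-05), as did Insm1 (1.07 ± 0.16) and Enpp2 (1.09 ± 0.16), while Cubn (-0.98 ± 0.16) and Gata6 (-1.34 ± 0.34) fell. For these genes KO+WT differed from f/f in the same direction as from KO. Sfmbt2 (-0.12 ± 0.31, adjusted p = 0.86) and Dll1 (0.23 ± 0.27, adjusted p = 0.644) did not differ past the threshold. Cyr61 (1.00 ± 0.23) and Id2 (1.24 ± 0.36) were higher than in f/f, as in KO. Feeder markers rose, 11 of 16 (13 adjusted over the list alone), with Col3a1 at 1.06 ± 0.14 and Col1a1 at 0.89 ± 0.17, and 19 of 26 ribosomal protein genes fell (26 over the list alone), with Rpl13 at -0.62 ± 0.06. With an estimated correlation the adjusted p was 0.235 and 0.951. By size, 90 genes were higher and 34 lower at 3i, 61 and 49 at day 1, and 39 and 10 at day 2. With a minimum of 10 CPM the totals were 68, 59 and 29, in place of 124, 110 and 49, and without day 1 175 genes passed across states, in place of 1368.

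KO+N-KR against KO gave 999 genes that rose and 1347 that fell. Sfmbt2 (-1.99 ± 0.30, adjusted p = 0.000886) and Cdkn2a (-1.41 ± 0.19, adjusted p = 0.000428) fell and Insm1 (2.09 ± 0.18) and Dll1 (1.59 ± 0.30) rose, as they did in KO+WT, although Eed itself did not pass the test. Xlr5a fell (-6.15 ± 0.25), and so did Fundc1 (-3.71 ± 0.13). The endoderm difference was smaller than against KO+WT: 6 of 18 genes rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.28 and Cubn at 0.67 ± 0.14 (camera adjusted p = 0.00753, and 0.764 with an estimated correlation). Of 8 parietal endoderm genes 4 rose (6 over the list alone, median 0.33, camera adjusted p = 0.000689, and 0.76 with an estimated correlation). Of 7 2-cell-like genes 6 fell (6 over the list alone, median -1.78, camera adjusted p = 4.17e-05, and 0.76 with an estimated correlation). Camera also called general pluripotency (5 of 10 rose; 5 and 1 fallen over the list alone), formative (4 of 15 rose, 1 fell; 7 and 1 over the list alone) and WNT feedback genes (5 of 12 fell; 5 and 1 risen over the list alone), each at an adjusted p of 0.0237, and 0.76, 0.874 and 0.764 with an estimated correlation. Without day 1 328 genes passed and without day 2 1105, and with KO and KO+N-KR alone 904, in place of 2346.

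Fitted over the 24 libraries, where the error is near that of repeated sequencing, far more genes passed, and these counts describe the RNA samples, not the genotypes. For KO against f/f 2494 genes were higher and 2848 lower at 3i, 1842 and 2086 at day 1, and 2648 and 3073 at day 2. Under library totals alone these splits were 3266 and 2103, 2539 and 1475, and 3546 and 1904. For KO+WT against KO they were 2385 and 2041, 2402 and 2625, and 3331 and 3126, and under library totals alone 2011 and 2410, 2197 and 2817, and 2921 and 3440. For KO+N-KR against KO+WT they were 1328 and 1518, 866 and 1105, and 836 and 570, and under library totals alone 1149 and 758 at day 1 and 611 and 811 at day 2. For KO+WT against f/f they were 2888 and 2888, 2075 and 2410, and 1432 and 1886 (under library totals alone 3196 and 2527, 2566 and 2033, and 2178 and 1327). In f/f, 4625 genes were higher and 4785 lower at day 1 than at 3i, and 4769 and 4581 at day 2. Under library totals alone these were 3794 and 5721, and 4291 and 5125, so the larger side turned at day 2. DESeq2 passed 2754, 1854 and 3013 genes for KO against f/f, 2265, 2817 and 3684 for KO+WT against KO, 1131, 779 and 423 for KO+N-KR against KO+WT, and 3402, 2449 and 1419 for KO+WT against f/f. Leaving out replicate 1 of either group lowered the totals by over 1.5 times for KO against f/f at day 1 (2613 without f/f, 2539 without KO, of 3928) and for KO+N-KR against KO+WT at 3i (1699 without KO+WT, 1755 without KO+N-KR, of 2846), day 1 (1113 and 1165, of 1971) and day 2 (811 and 649, of 1406).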

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

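The tests on feeder cells, on depth and composition, and on the share of endoderm-like cells below were chosen after the result was seen, and the others before. The change from 3i differed between KO and f/f in 1464 genes at day 1 and 3849 at day 2, and between KO+N-KR and KO+WT in 1410 and 1831, by the interaction term over the 24 libraries. As the error there is near that of repeated sequencing, the sizes are given too: by at least 2-fold, 39 genes were higher and 40 lower at day 1 for KO, and 230 and 52 at day 2. For KO+N-KR they were 101 and 31 at day 1 and 68 and 38 at day 2.

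Of the 198 genes higher in KO at day 2, the median log2 ratio of KO+WT over f/f was 0.26 (quartiles -0.04 and 0.51), while feeder markers lay at 1.11 in KO+WT and 0.57 in KO, so more feeder cells did not account for them. Of the 198, 93 (47%) lay under 10 CPM in KO, but 206 genes at least 2-fold higher in replicate 1 lay above all genes by a median of 1.13 (quartiles 0.94 and 1.49) in replicate 2. Sampling noise of low depth or 1 scaling factor for the sample did not account for that difference. A first test, the median of all genes, was replaced because the scaling holds it near 0. Of the 198, 83 (41.9%, exact 95% interval 35 to 49.1) lay at least 1.5-fold above the highest f/f sample. The interval takes genes of 1 sample as independent, which they need not be. A slower exit from 3i and an effect of Eed loss cannot be told apart by this share.

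Endoderm genes were higher in KO+N-KR than in KO+WT, and fewer feeder cells would raise genes of all other cells alike. The endoderm list lay above 40 pluripotency genes by 1.17 (bootstrap interval 0.80 to 1.39), so in these samples fewer feeder cells did not account for the difference. This replaced a first test on 4 shared markers, all of them in the endoderm list. Bootstrap intervals here resampled genes, which can move together, from 1 line per genotype. They do not measure the spread between lines. Against f/f the list had a median of 0.50 in KO+N-KR (bootstrap interval 0.26 to 0.88, 7 genes higher and 0 lower). In KO+WT against f/f it was -0.35 (5 genes fell and 1 rose, camera adjusted p = 0.0576). Against KO the medians were 0.28 in KO+N-KR and -0.69 in KO+WT. KO+N-KR and KO+WT thus lay on opposite sides of f/f. But f/f was grown without tamoxifen, and KO itself lay above f/f by a median of 0.32. Against KO, treated like both lines, KO+WT lay further off than KO+N-KR. Camera for KO+N-KR against KO gave an adjusted p of 0.00753, and 0.764 with an estimated correlation. A low KO+WT line as the main source of the endoderm difference can therefore not be excluded. A first test of a larger share of endoderm-like cells counted positive fold changes within the list itself (17 of 18), and was replaced because those genes are the pattern itself. In its place, 10 other textbook endoderm genes had a median of 0.10 (bootstrap interval 0.01 to 0.59, 8 positive, 0 past the threshold), by which a larger share of such cells and a change within cells cannot be told apart.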

How the results depend on the processing

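Across states, the cause of the changes below was not tested unless fewer samples or a stricter threshold made them. Fos in KO against f/f reversed without 3i (-0.034, range -0.034 to 0.862 as 1 state was left out), and Sfmbt2 in KO+WT against f/f without day 1 (0.001, range -0.191 to 0.001), and neither passed the threshold in any of these. Leaving out a state gave 0 to 1362 genes for KO against f/f, 225 to 2852 for KO+WT against KO, 30 to 98 for KO+N-KR against KO+WT, 175 to 1490 for KO+WT against f/f and 328 to 2934 for KO+N-KR against KO. Leaving out a genotype gave 8704 to 9342 at day 1 and 8220 to 9086 at day 2. KO against f/f gave 808 genes with replicate 2 libraries and 782 with the compared groups alone, KO+N-KR against KO 904, and KO+N-KR against KO+WT 200, and 132 in DESeq2. At 2-fold or more, 118, 248, 37, 162 and 241 genes were left for the 5 genotype comparisons and 2715 and 2714 for day 1 and day 2. With an estimated correlation 3 fixed list tests passed. Over 24 libraries DESeq2 gave 2754, 1854 and 3013 for KO against f/f, 2265, 2817 and 3684 for KO+WT against KO, 1131, 779 and 423 for KO+N-KR against KO+WT, 3402, 2449 and 1419 for KO+WT against f/f, and 476, 1690, 488 and 662 for the interactions. At 2-fold or more these were 231, 224 and 670, 291, 521 and 732, 231, 173 and 99, 400, 355 and 248, and 103, 469, 152 and 115, with 2520 and 2550 for f/f at day 1 and day 2. Leaving out 1 library gave, by state, 3974 to 4385, 2539 to 3103 and 4242 to 4872 for KO against f/f, 2970 to 3628, 3484 to 4283 and 4845 to 5594 for KO+WT against KO, 1699 to 2254, 1113 to 1530 and 649 to 1033 for KO+N-KR against KO+WT, 4199 to 4945, 3082 to 3729 and 2220 to 2627 for KO+WT against f/f, 8222 to 8675 and 8077 to 8600 for embryoid bodies in f/f, and 972 to 1268, 2978 to 3462, 873 to 1176 and 1222 to 1532 for the interactions. List tests passed in 126 to 132 and 5 to 6 cases, and Eed in KO at 3i lay between -0.41 and -0.31. The lone library was assumed to vary like the other groups. A minimum of 10 CPM gave 36, 27 and 115 genes by size for KO against f/f, 41, 119 and 175 for KO+WT against KO, 26, 25 and 12 for KO+N-KR against KO+WT, and 68, 59 and 29 for KO+WT against f/f. A block for pairs of same-numbered libraries gave 5380, 3957 and 5751 genes for KO against f/f and left Eed at -0.35, and the deviations of such pairs correlated by -0.03 to 0.05. Of 291 gene values over 24 libraries 247 kept their call in all settings and 0 reversed, and of 175 across states 72 and 2.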

Other observations

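The test on reads moved between copies below was chosen after the result was seen, and the others before. The Xlr genes, a cluster of near-identical X-linked copies, were near 0 in both lines with re-expressed EED. Summed over 11 genes, they stood at 183, 163 and 163 CPM in f/f at 3i, day 1 and day 2, and at 170, 142 and 156 CPM in KO. In KO+WT they stood at 7.87, 12.2 and 8.83 CPM, and in KO+N-KR at 6.15, 7.90 and 5.20 CPM. The sum in KO+WT was lower than in KO by a log2 ratio of at most -3.54 in each state, so reads moved between copies did not account for it. The nearest 20 expressed neighbours had a median of 0.03 (quartiles -0.12 and 0.10, 4 past the threshold), so a lower yield of the region did not either. In f/f, where Eed was not deleted, the sum lay near that of KO in each state. For these 11 genes this argues against the mere presence of EED as the cause. Whether the cause lay in the history of both rescue lines or in the re-expression itself was not tested.

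Regrouping the samples of 2 genotypes gave 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes as observed. The real split and the highest other gave 1380 and 5 genes for KO against f/f, 2422 and 0 for KO+WT against KO, 84 and 0 for KO+N-KR against KO+WT, 1368 and 0 for KO+WT against f/f, and 2346 and 7 for KO+N-KR against KO. Of 35 splits of 8 samples, 1 gave as many genes at day 1 against 3i (9898, highest other 0) and 1 at day 2 (9560, highest other 0). All these splits ignore the pairing of samples by state or by genotype. A split that mixes the compared groups moves their difference into the error, so low counts there were built in. The shares are therefore no measure of chance.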
